A study of Bos taurus with 7 samples.

How the data were processed

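Plasma RNA from 7 Japanese-Black cows (Bos taurus) was compared on day 21 after artificial insemination, 4 cows labelled pregnant and 3 labelled non-pregnant, each cow on its own 1-colour microarray. Per the labels' protocols, RNA was extracted with a serum and plasma kit and 50 ng was labelled with the dye Cy3. Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1, and the design places probes on the bovine assembly UMD 3.1 (bosTau6). The arrays carry 744 bovine miRNAs through 1617 probes and 14880 spots, besides 715 control spots. Per the file headers, the deposited spot intensity is background-subtracted within each array and is not scaled between arrays. The deposited intensity per miRNA is the sum of its probes' signals, set to 0.1 by the software where the miRNA was not called detected.

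The authors also deposited a table of log2 values for the same arrays. Set against the scanner files, 730 of the 744 miRNA names matched, and every matched value lay at log2 of the intensity per miRNA plus 3.32 on all arrays, to within 7.4e-06. That table is therefore unscaled between arrays and blank where a miRNA was not detected, and its column medians were 7.29, 7.64, 7.40 and 7.25 for pregnant 1 to 4, and 7.90, 7.75 and 7.46 for non-pregnant 1, 3 and 4. What the constant stands for is not given in the sources used here.

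Spots flagged as outliers (558 to 1149 per array) and control spots were left out, and no spot was saturated. The remaining spots of a probe were averaged, divided by the 75th percentile of the array over the 57 probes detected on all arrays (over 50% of a probe's spots well above background), floored at a scaled value of 0.0122 (log2 -6.36), and put on the log2 scale. The floor is the median over arrays of the lowest scaled value among detected probes. That lowest value ran from 0.00518 in pregnant 3 to 0.0519 in non-pregnant 1. The floor thus lay above some detected signals on the brighter arrays and below the lowest detected signal on the dimmer ones. Differences of dim miRNAs may therefore follow array brightness in part. A miRNA's level is the mean over its probes, and values at the floor have no order among themselves. miRNAs called detected by the software on at least 3 of the 7 arrays were tested (88 miRNAs). limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg threshold 0.05) compared pregnant with non-pregnant cows with no covariate. Lists of miRNAs with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, which asks whether members ranked above the other tested miRNAs. Measures with a single value per array were compared with a two-sided exact permutation test over all 35 splits of the 7 arrays into 4 and 3, whose smallest p is 0.0286. Where no probe of a miRNA was well above background on any array of a group, no fold is given for it, and its log2 differences depend on the floor. A difference within 1e-09 of 0 was counted as neither positive nor negative.

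The groups, tests, 14 miRNA lists, the rule for named miRNAs and the other settings to be tried were fixed before the data were examined. The rule took all miRNAs past the threshold, otherwise the 10 with the smallest p in each direction, every tested member of the erythrocyte list and of a list of earlier blood candidates for cattle pregnancy, the 5 highest levels, and miRNAs detected on every array of one group and none of the other. It named 30 miRNAs. The alternatives changed the scaling, background correction, summary of spots, filter, floor, variance model, array weights and test. They also took cow number as a block and left out each array in turn. Normexp background correction added an offset of 50 to every spot before scaling, while the lowest signals of detected probes were 7.36 to 10.0 per array. Differences of dim miRNAs with normexp therefore rest largely on the scaling divisor.

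The procedure was tested on simulated data with the spread of these 88 miRNAs, drawn independently of each other in 100 runs. No floor was applied to the simulated levels, and changes went in both directions. The shares called therefore do not hold for miRNAs at or near the floor, where they are likely too high. Of 20 miRNAs changed per run, limma called 60.3% of those changed by log2 1, 88.7% by log2 2 and 97.7% by log2 3, with 1.02 unchanged miRNAs called per run, and 10 of 100 runs with no change at all gave a call. Of 100 simulated lists of 7 unchanged members, camera at the preset correlation called 3 when members were independent and 43 when they shared a correlation of 0.8, and none of the latter with the correlation estimated. The estimated correlation was not tried on shifted lists, so how often it finds a true shift is not known.

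All 7 arrays came from 1 slide and 1 scan date. Pregnant cows lay in slide row 1 and non-pregnant cows in slide row 2, so row and group cannot be told apart. The small number of arrays limits the precision: the median 95% interval of a miRNA's log2 difference reached 0.60 to either side. Gene overlaps come from a RefSeq table on the assembly ARS-UCD2.0, of which no coordinates were used, and positions are those of the probe's match on UMD 3.1 in the scanner files. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.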

Results

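Circulating miRNAs were measured in the plasma of 7 inseminated Japanese-Black cows to compare early pregnancy with its absence on day 21. There were 4 pregnant and 3 non-pregnant cows, each a separate animal. Of 744 bovine miRNAs on the array, 124 were detected on at least 1 array, 40 on all 7 and 620 on none. The summed miRNA signal ranged from 12080 (non-pregnant 1) to 101065 (pregnant 3).

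More miRNAs were detected in the plasma of pregnant cows, a difference that passed its own test but not after adjustment. The 4 pregnant arrays detected 90, 93, 101 and 91 miRNAs and the non-pregnant arrays 45, 84 and 81, a mean of 93.8 ± 4.99 (SD, n = 4) against 70.0 ± 21.7 (SD, n = 3). Every pregnant array exceeded every non-pregnant array (exact permutation p = 0.0286, the smallest possible, and 0.0571 after Benjamini-Hochberg adjustment over the 2 tests per array). miR-29b, of a family that represses collagen genes, was the only miRNA called detected by the software in 4 of 4 pregnant and 0 of 3 non-pregnant cows, though well above background in only 1 of the 4 (Fisher's exact p = 0.0286, two-sided), and 9 of the 35 splits of the arrays gave at least 1 such miRNA, with a highest count of 2. The log2 total signal did not separate the groups, at 15.37 ± 0.89 (SD, n = 4) in pregnant and 15.17 ± 1.40 (SD, n = 3) in non-pregnant cows (exact permutation p = 0.857). Without non-pregnant 1 the difference in detected miRNAs was 11.3 in place of 23.8, and counting miRNAs by spots well above background it was 13.8 (exact permutation p = 0.114). The difference in log2 total signal, 0.21, turned to -0.60 without non-pregnant 1 and to -0.21 without pregnant 3.

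**Figure D1:**
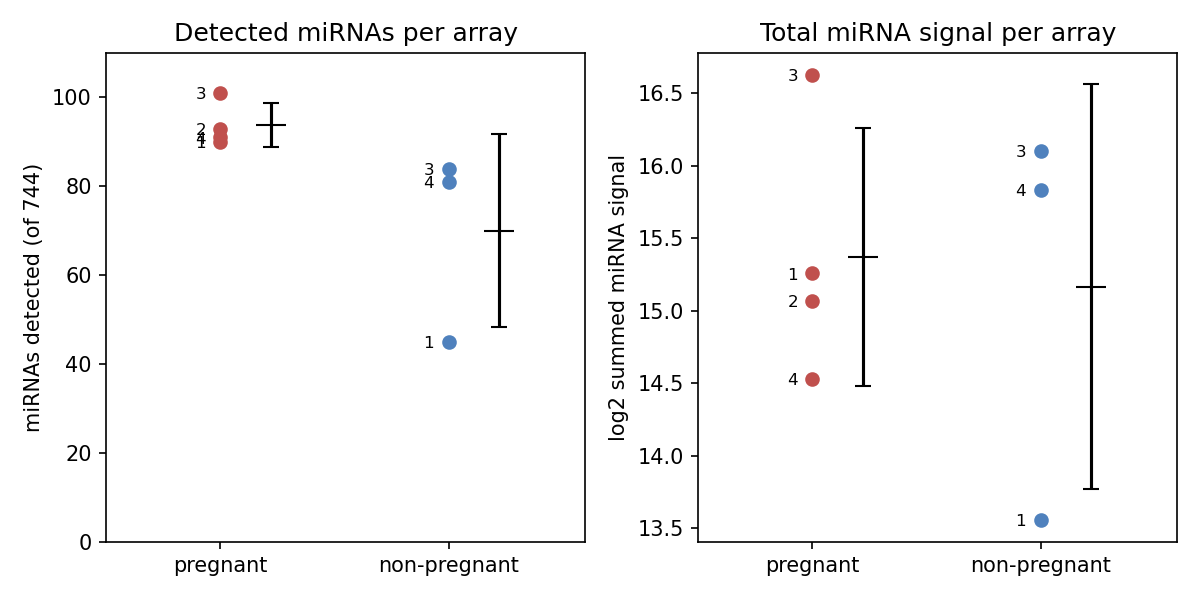
Left, number of miRNAs called detected per array (of 744); right, log2 of the summed miRNA signal. Points are arrays labelled by cow number and bars are group mean ± SD (n = 4 pregnant, n = 3 non-pregnant). Pregnant arrays lie between 90 and 101 detected miRNAs and non-pregnant arrays between 45 and 84, while total signals overlap.

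A few miRNAs with very short, C-rich probes carried most of the signal in both groups. miR-1777a, miR-1777b, miR-2305, miR-2328-3p, miR-1584-5p, miR-2412, miR-2888 and miR-2881 together took 89.6% ± 2.33 (SD, n = 4) of the signal in pregnant and 91.7% ± 0.811 (SD, n = 3) in non-pregnant cows (exact permutation p = 0.229). miR-1777b (probe CCCCGCCCCCC, chromosome 7, 63524577 to 63524586, its gene overlapping PDGFRB on ARS-UCD2.0) had a log2 level of 3.28 ± 0.10 (SD, n = 4) in pregnant and 3.41 ± 0.11 (SD, n = 3) in non-pregnant cows. The probe of miR-1777a, CCCGCCCCCCA (chromosome 6, 107199025 to 107199034), is nearly the same run of C, so the 2 levels are uncertain as separate measurements. miR-223, a miRNA of myeloid cells, was the brightest blood-cell miRNA and took between 0.137% and 1.50% of the signal.

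No single miRNA passed the test between pregnant and non-pregnant cows. The largest differences among named miRNAs were in miR-19b, of the growth-promoting miR-17-92 cluster, and miR-142-5p, a miRNA of blood-forming cells. miR-19b had a log2 level of -4.49 ± 1.13 (SD, n = 4) in pregnant and -5.67 ± 0.30 (SD, n = 3) in non-pregnant cows, a difference of 1.18 with a standard error of 0.61 (2.26-fold). miR-142-5p was at -4.57 ± 0.95 (SD, n = 4) against -5.74 ± 0.08 (SD, n = 3), a difference of 1.17 with a standard error of 0.51 (2.25-fold). It was not called detected in non-pregnant 1, whose value of -5.68 enters that mean, SD and fold. Both miRNAs were well above background in 4 of 4 pregnant and 2 of 3 non-pregnant cows, so the sizes of their differences are uncertain. With normexp background correction the differences were 0.083 and 0.026, and with an array left out they ran from 0.80 to 1.62 and from 0.83 to 1.45. limma found 0 of 88 tested miRNAs past the threshold, with a smallest adjusted p of 0.743, and 1 at an unadjusted p under 0.05, miR-2436-5p (log2 0.34, standard error 0.13). The difference of miR-2436-5p was negative with quantile scaling, normexp, scaling on probes of low GC content and in the deposited table (-0.19), and was 0 with the floor doubled. The unadjusted count was 11 without pregnant 3, 2 without pregnant 1, non-pregnant 1 or non-pregnant 4, 1 without non-pregnant 3 and 0 without pregnant 2 or pregnant 4. Per-miRNA exact permutation tests gave 0 at an unadjusted p under 0.05.

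The next miRNAs on the pregnant side by p were miR-140 (log2 0.42, standard error 0.21), miR-320a (0.33), miR-296 (0.25), miR-29a (0.54), miR-2407 (0.26) and miR-106b (0.61). With an array left out, these ran from 0.26 to 0.54, 0.22 to 0.46, 0.11 to 0.38, 0.37 to 0.80, 0.19 to 0.37 and 0.37 to 0.81 in that order, and all 6 were negative with normexp. miR-106b was at the floor in all 3 non-pregnant and 2 of 4 pregnant cows, so the size of its difference depends on the floor. miR-140, miR-320a and miR-2407 were each at the floor in 2 of 3 non-pregnant cows. miR-320a and miR-2407 were also there in 1 of 4 pregnant cows. The sizes of their differences depend on the floor as well. miR-19a (chromosome 12, 66226887 to 66226906) was well above background in 2 of 4 pregnant and 0 of 3 non-pregnant cows, with the other 2 pregnant cows at the floor, so no fold is given. On the other side stood miR-2486-5p (log2 -0.35, standard error 0.34), miR-1777a (-0.27), miR-2374 (-0.18), miR-2902 (-0.16), miR-1777b (-0.13), miR-2888 (-0.11), miR-2305 (-0.10) and miR-2413 (-0.10), which, miR-2486-5p apart, turned positive without scaling, and with miR-181d not well above background in any cow and miR-1225-3p in 1 of 4 pregnant and 0 of 3 non-pregnant cows. With an array left out, miR-2486-5p ran from -0.64 to -0.058, miR-1777a from -0.48 to -0.071 and miR-2902 from -0.28 to -0.077. miR-1777b ran from -0.19 to -0.082, miR-2888 from -0.24 to -0.031 and miR-2305 from -0.25 to -0.0030, while miR-2374 and miR-2413 crossed 0. Of the 30 named miRNAs, only the interval of miR-2436-5p left out 0. Of the 88 tested miRNAs, 62 had a positive difference, 43 with quantile scaling, 76 without scaling, 54 with the software's signal per miRNA, 8 with normexp background correction and 34 with scaling on probes of low GC content, a setting chosen after the data were seen. The median difference was 0.18, 0.00, 0.20, 0.24, -0.19 and -0.078 in that order. With the floor doubled, 46 of the 88 were positive (median 0.016). With only the 40 miRNAs detected on all 7 arrays, 19 were positive (median -0.0030). No lean to the positive side was thus seen among miRNAs detected on every array. In the main run, the 18 tested miRNAs at the floor on every non-pregnant array could not have a negative difference.

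**Figure D2:**
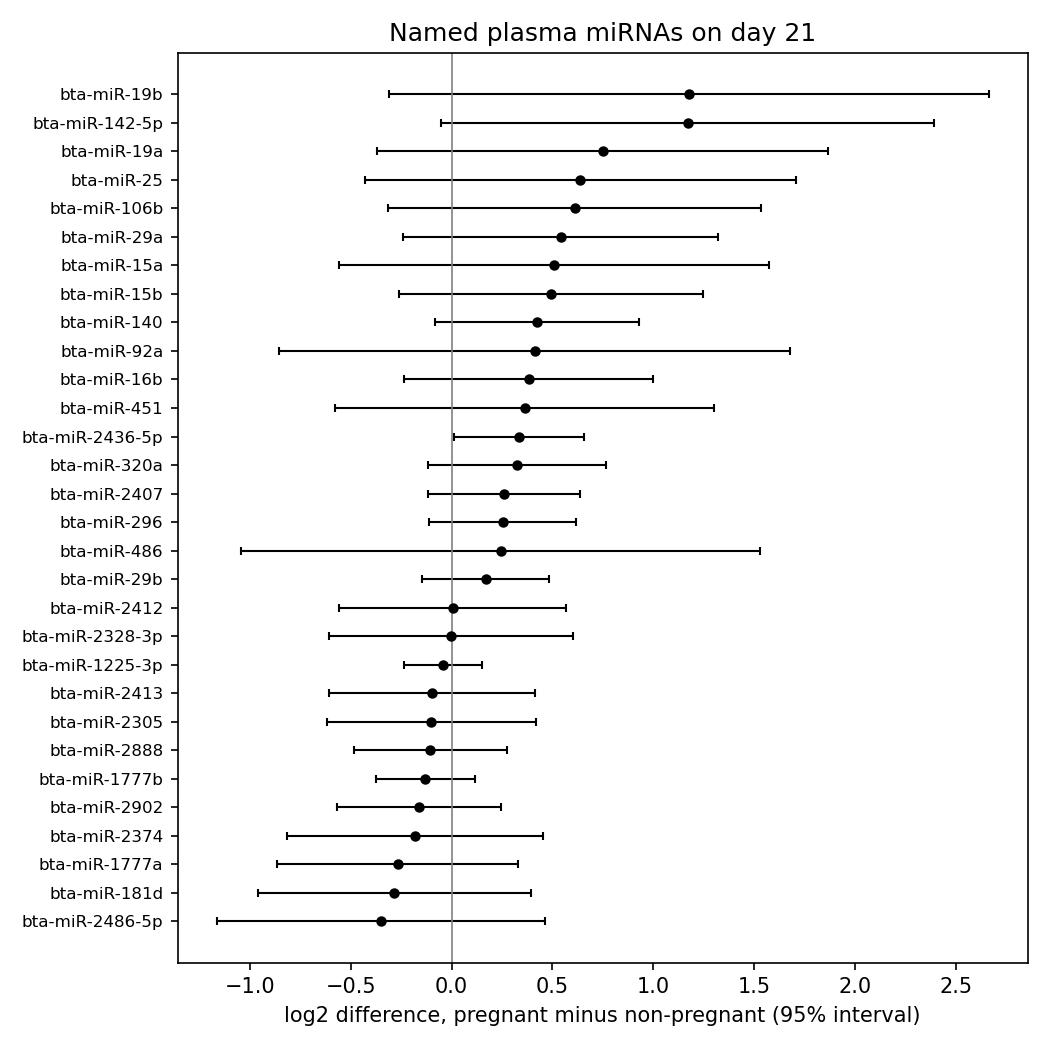
Log2 difference in level, pregnant minus non-pregnant, of the 30 named miRNAs (points) with 95% intervals from limma (bars), n = 4 and n = 3. Only the interval of miR-2436-5p leaves out 0, and its difference became 0 with the floor doubled, as did that of miR-2407. The values of miR-19a, miR-29b, miR-181d and miR-1225-3p, not well above background in non-pregnant cows, and of miR-106b and miR-15b, at the floor there, depend on the floor. Those of miR-140, miR-320a and miR-2407, at the floor in 2 of 3 non-pregnant cows, depend on it in part.

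Leukocyte miRNAs and the miR-17-92 cluster ranked above the other miRNAs in pregnant cows as groups with camera's preset correlation, but no list passed with an estimated one in any of the 22 settings run (smallest adjusted p = 0.130, without scaling). How often an estimated correlation would find a true shift was not tested, so a list that fails it is not shown to be unchanged. Of 16 leukocyte miRNAs on the array, only 6 were detected on at least 1 array and 5 were tested. For the miR-17-92 cluster and its copies, 9 of 15 were detected and 7 tested. All 5 tested leukocyte miRNAs were on the pregnant side (2 of 5 with normexp background correction), led by miR-142-5p and by miR-223 (chromosome X, 99936372 to 99936391, log2 1.13, standard error 0.80), with miR-29a at 0.54, miR-27a-3p at 0.34 and miR-23a well above background in 1 of 4 pregnant and 0 of 3 non-pregnant cows. The list mean was 0.70 (0.026 with normexp), which is 0.52 above the median of all tested miRNAs (camera adjusted p = 0.0461, and adjusted p = 0.557 with an estimated correlation). All 7 tested members of the miR-17-92 cluster and its copies were also on that side (1 of 7 with normexp), among them miR-19b, miR-20a (log2 1.00, standard error 0.71), and miR-25 (0.64) and miR-106b (0.61), which both overlap MCM7, a replication gene, on ARS-UCD2.0. Their mean was 0.71, 0.53 above the median (camera adjusted p = 0.0461, and adjusted p = 0.557 with an estimated correlation), but -0.074 with normexp background correction, where it stayed 0.11 above the median and no longer passed (adjusted p = 0.171). miR-23a of the leukocyte list and miR-17-5p, miR-19a and miR-106b of the cluster list were at the floor in all 3 non-pregnant cows. Their differences could not be negative in the main run, so the counts of members on the pregnant side were partly fixed in advance. miR-27a-3p was at the floor in 2 of 3 non-pregnant and 1 of 4 pregnant cows, so the size of its difference also depends on the floor. None of the members of either list passed alone or adjusted over the list alone. Leaving out pregnant 2, pregnant 3, pregnant 4, non-pregnant 3 or non-pregnant 4 gave 0 lists past the threshold, and leaving out pregnant 1 gave 5 and non-pregnant 1 gave 4. The scaled levels were high in pregnant 2 and pregnant 4. The leukocyte mean was -4.02 and -4.17 there, and -5.20 and -5.41 in pregnant 1 and 3. In non-pregnant 1, 3 and 4 it was -5.02, -5.66 and -5.51 (exact permutation p = 0.229 between the groups). Without scaling, the mean of the members of both lists was 3.92, 4.64, 4.43 and 4.47 in pregnant 1 to 4. Pregnant 3 was thus near pregnant 2 and 4 before division by its 75th percentile, which was 1645 against 606, 442 and 415 in pregnant 1, 2 and 4.

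Without scaling between arrays, as in the deposited table, the mean level of the 12 miRNAs of these 2 lists was higher in each pregnant cow than in every non-pregnant cow. It was, in log2, 4.36 ± 0.31 (SD, n = 4) in pregnant and 3.67 ± 0.23 (SD, n = 3) in non-pregnant cows (exact permutation p = 0.0571). The lowest pregnant value was 3.92 and the highest non-pregnant value 3.85. miR-23a, miR-17-5p, miR-19a and miR-106b were at the floor of this scale (log2 3.09) in all 3 non-pregnant cows. Their differences could not be negative on this scale either, which limits what the separation shows. On this scale miR-30d (chromosome 14, 8080307 to 8080320) had the smallest adjusted p of limma, 0.101, with a log2 difference of 0.64 and a standard error of 0.11, ahead of miR-19b (1.21) and miR-24-3p (0.98). The non-pregnant level of miR-30d, 3.12 ± 0.025 (SD, n = 3), lay next to the floor, so its small standard error and rank depend on the floor. In the main run miR-30d was at the floor in 2 of 3 non-pregnant cows. limma then called 0 miRNAs, 10 at an unadjusted p under 0.05, and camera 5 lists at the preset correlation and 0 with an estimated one.

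**Figure D3:**
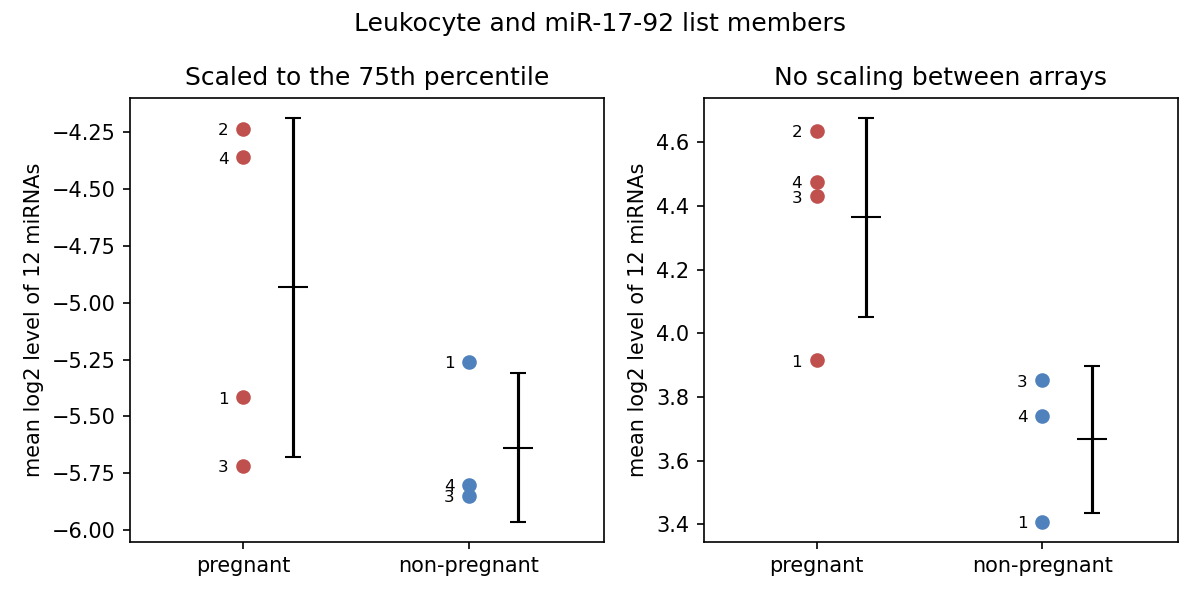
Mean log2 level of the 12 members of the leukocyte and miR-17-92 lists per array, scaled to the 75th percentile (left) and without scaling (right). Points are arrays labelled by cow number and bars are group mean ± SD (n = 4 and n = 3). Without scaling, pregnant arrays lie at 3.92 or above and non-pregnant arrays at 3.85 or below; with scaling they overlap.

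Red-cell miRNAs leaned the same way, and whether this and the remaining lists passed at the preset correlation depended on the setting; with an estimated one none passed in any setting. All 8 tested members of the erythrocyte and haemolysis list had positive differences (mean 0.46, camera adjusted p = 0.0958), with miR-451 at 0.36 (standard error 0.39), miR-486, within ANK1 on ARS-UCD2.0, at 0.24 (0.53), miR-92a at 0.41, miR-15a at 0.51, miR-15b at 0.49 (at the floor in all 3 non-pregnant and 2 of 4 pregnant cows) and miR-16b at 0.38; the list mean was -0.12 and all 8 were negative with normexp. The list passed with quantile scaling, without scaling, with the software's signal per miRNA, with the floor doubled, without pregnant 1 or non-pregnant 1, and in the settings added later, low-GC scaling and brightness as a covariate (adjusted p = 0.000950 to 0.04996 at the preset correlation; in the main run adjusted p = 0.561 with an estimated one). It shares miR-25, miR-92a and miR-106b with the cluster list. Of its 13 members on the array, 11 were detected on at least 1 array and 8 tested. miR-15b and miR-106b, at the floor in all 3 non-pregnant cows, could not have a negative difference in the main run. With an array left out, miR-451 ran from 0.15 to 0.63, miR-486 from -0.12 to 0.70 and miR-92a from 0.0038 to 0.997. miR-15a ran from 0.29 to 0.78, miR-15b from 0.30 to 0.66 and miR-16b from 0.25 to 0.53. The 4 tested members of the miR-29 and miR-30 families had a mean of 0.43 (adjusted p = 0.0903) and the 3 of the let-7 family 0.44 (adjusted p = 0.132), which turned to -0.16 and -0.18 with normexp. Of these, miR-29b, miR-29c and let-7i were not well above background in non-pregnant cows. They and let-7g were at the floor in all 3 non-pregnant cows, so their differences could not be negative in the main run. The former list passed with quantile scaling, without scaling, with the software's signal, without the filter, with the floor halved, without pregnant 1, and with low-GC scaling and the brightness covariate (adjusted p = 0.00507 to 0.0404), and let-7 without pregnant 1 (adjusted p = 0.0404). The platelet list, with miR-24-3p at 0.67 and miR-197 at -0.17, did not pass (adjusted p = 0.962), but did with normexp (adjusted p = 5.52e-05), without scaling (adjusted p = 0.0192, and 0.130 with an estimated correlation) and without non-pregnant 1 (adjusted p = 0.0399), and shares miR-223 with the leukocyte list. Only 3 of the 17 platelet miRNAs on the array were tested, and 7 were detected on at least 1 array. Of the earlier cattle candidates, miR-25 and miR-16b were tested and neither passed.

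miRNAs of other tissues were detected to different extents. Of 8 liver miRNAs, 4 were detected on at least 1 array. miR-122, the main liver miRNA, differed by 0.33 (standard error 0.86), and by 1.57 (standard error 0.70, adjusted p = 0.454) in the deposited table, which leaves pregnant 3 blank as undetected; the liver member miR-192 was well above background in 1 of 4 pregnant and 0 of 3 non-pregnant cows, and the epithelial member miR-375 in none of the 7. miR-223 was the only tested member of the interferon and inflammation list. None of 7 muscle and heart miRNAs and none of 52 miRNAs of the placenta-rich DLK1-DIO3 cluster was detected on any array, nor were more than 1 of 12 vascular and 1 of 49 miR-2284 and miR-2285 miRNAs.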

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

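The tests on haemolysis (miR-451 and miR-486 against the leukocyte list), scaling, probe base composition, and brightness in non-pregnant 3 and 4 were chosen after the results were seen. Of 38 values checked for a pregnant array far from the other 3, chance alone flags about 1 in 20. miR-92a in pregnant 3 was at -4.69, against -3.77 to -3.68 in the other pregnant cows (gap over range 0.915). miR-181d was at -6.10 in pregnant 4 and at the floor in the others, which fixes its ratio at 1, and no cow had it well above background. None of 18 kinds of control probe was brighter on every pregnant array than on every non-pregnant array.

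With 0 single miRNAs in the real split, counting splits decides nothing, since all 35 necessarily gave at least 0. The highest other split gave 12. That split set pregnant 3, non-pregnant 3 and non-pregnant 4, the 3 brightest arrays, against the rest, and the next, with 10, set the 3 dimmest against the rest. This points to a structure of the scaled levels that follows array brightness. Its source was not tested.

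The leukocyte and miR-17-92 lists passed the threshold together at the preset correlation, but not with an estimated one (adjusted p = 0.557 for both). Chance cannot be excluded, since 5 of the 35 splits, the real one included, gave 2 or more lists and the highest other split gave 5. Haemolysis stays open: miR-451 and miR-486 shifted 0.395 less than the leukocyte list (-0.395, exact permutation p = 0.2). The haemolysis index fixed beforehand, log2 miR-451 minus log2 miR-23a, differed by 0.059 between the groups (exact permutation p = 0.857). It decides little, since miR-23a was at the floor in 2 of 4 pregnant and all 3 non-pregnant cows. Scaling stays open too. Without scaling the shift was 0.696 (exact permutation p = 0.0571), and both lists passed at the preset correlation (adjusted p = 0.00136 for leukocyte and 0.000950 for miR-17-92) but not with an estimated one (adjusted p = 0.130 for both, a test added later). Pregnancy itself and slide row, which follows group, were not tested.

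G-rich miRNAs, read by C-rich probes, dominated the signal. miRNAs with CCCC in the probe were detected on all 7 arrays in 14 of 36 cases, against 26 of 708 others (odds ratio 16.5, Fisher's exact p = 2.57e-10, with miRNAs not independent). This is consistent with an effect of probe base composition, though a true abundance of such RNAs stays open. The 14 cases include the 8 brightest miRNAs, whose C-rich probes were seen before the test was chosen, so its p is not independent of that observation. No biological explanation was tested.

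More miRNAs were detected in pregnant cows. For non-pregnant 3 and 4, dimness in total signal is argued against for the software's calls. In 6 of the 8 pairs with a pregnant array, the pregnant array had less total signal and more miRNAs. The 2 pairs with pregnant 3, which was brighter, decide nothing. By spots well above background, a pregnant array with less total signal had more miRNAs in 3 of 8 pairs. Non-pregnant 3 then had 72 miRNAs, more than pregnant 1, 2 and 4 (69, 71 and 69), and so no lower count to account for against them. The 8 brightest miRNAs carried 92.4% and 91.7% of the signal on non-pregnant 3 and 4. Total signal therefore cannot tell whether the other miRNAs were dimmer there, which stays open. For non-pregnant 1, dimness may account for the count: the mean profile of the others dimmed to its level put 37 miRNAs above its lowest detected signal, against 36 observed by spots, 32 of them shared. Pregnancy and slide row stay open and cannot be told apart.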

How the results depend on the processing

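Scaling on probes of low GC content, brightness as a covariate and the unadjusted limma counts were chosen after seeing the data. The count of 0 differentially abundant miRNAs held in every run of limma. The permutation test also gave 0, but it would have needed 51 of the 88 miRNAs at its smallest p to call any. Unadjusted, the count was 1 by limma and 1 by a two-group test with equal variances. By limma it was 10 without scaling, 9 with the software's signal, 7 with array weights, 6 with the deposited table, 4 with the floor halved, 2 with quantile or low-GC scaling, 11 with the brightness covariate, 0 with normexp, the floor doubled or only miRNAs detected on all 7 arrays, 0 to 11 with an array left out, and 1 in the other settings; the cause was not tested. The list count of 2 was 4 with quantile scaling, 5 without scaling, 4 with the software's signal per miRNA, 4 with scaling on probes of low GC content and 4 with brightness as a covariate. It was 1 with only miRNAs detected on all 7 arrays, where fewer lists could be tested, and 0 with medians of spots, trend and robust variances, array weights, an estimated correlation, or fry; leaving out arrays gave 0 to 5. With normexp it stayed 2, but the lists were platelet and leukocyte. With an array left out, the list mean ran from 0.27 to 0.69 for erythrocyte, 0.13 to 1.07 for platelet, 0.47 to 0.94 for leukocyte, 0.24 to 0.61 for let-7, 0.47 to 0.98 for miR-17-92 and 0.28 to 0.59 for miR-29 and miR-30. The estimated correlation, planned for the first setting only, was then run in all the others after seeing the data, and the count was 0 in each. With the cow number as a replicate block the list count was 0, and no count of single miRNAs changed. Number 2 occurred only among pregnant cows, so with the block pregnant 2 added nothing to the differences. The list means equalled those without pregnant 2, so the block was not a separate check on them. Deviations of same-numbered cows correlated at 0.094, 0.65 and -0.20, so the numbers were not taken as pairs. The difference in detected miRNAs was 13.8 by spots well above background and 11.3 to 30.8 with an array left out, where exact tests cannot fall below 0.05. The difference in log2 total signal ran from -0.60 to 0.67 with an array left out.

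Of 641 recomputed differences of named miRNAs, 72 changed sign, 562 kept it and 7 became 0 (within 1e-09), among them miR-2436-5p with the floor doubled, and no call changed; of the list means, 4 changed sign, 1 of which also lost its call, 20 gained and 19 lost a call in all, and 81 kept both. With normexp, the list means were -0.12 for erythrocyte, -0.18 for let-7, -0.074 for miR-17-92 and -0.16 for miR-29 and miR-30, and the turned log2 differences were -0.19 for miR-2436-5p, -0.18 for miR-140 and miR-320a, -0.22 for miR-296, -0.077 for miR-29a, -0.20 for miR-2407, -0.12 for miR-19a, -0.15 for miR-106b, -0.13 for miR-15a, -0.16 for miR-15b and miR-451, -0.17 for miR-16b, -0.052 for miR-25, -0.079 for miR-486, -0.042 for miR-92a, 0.036 for miR-2328-3p and -0.25 for miR-29b. Quantile scaling gave -0.092 for miR-2436-5p, -0.0070 for miR-296, -0.17 for miR-2407, 0.054 for miR-1777b, 0.030 for miR-1225-3p, -0.051 for miR-486, 0.025 for miR-2328-3p and -0.041 for miR-2412. The deposited table gave -0.19 for miR-2436-5p, -0.32 for miR-320a, -0.38 for miR-2407, 0.17 for miR-1777b, 0.038 for miR-1777a, 0.16 for miR-2902, 0.093 for miR-2374, 0.20 for miR-2888 and miR-2305, 0.11 for miR-2413 and 0.30 for miR-2328-3p. No scaling gave 0.17 for miR-1777b, 0.039 for miR-1777a, 0.14 for miR-2902, 0.12 for miR-2374, 0.20 for miR-2888 and miR-2305, 0.083 for miR-1225-3p, 0.055 for miR-2413 and 0.30 for miR-2328-3p. Low-GC scaling gave -0.069 for miR-2436-5p, -0.13 for miR-2407, 0.036 for miR-1225-3p, -0.14 for miR-486 and -0.37 for miR-2412. The software's signal gave 0.067 for miR-181d, 0.44 for miR-1225-3p, -0.071 for miR-486 and -0.34 for miR-2412. A lower floor gave 0.0059 for miR-1225-3p, array weights 0.055 for miR-2413 and -0.18 for miR-2412, medians of spots 0.014 for miR-2328-3p, the replicate block -0.11 and the brightness covariate -0.051 for miR-2412. With an array left out, ranges crossing 0 were -0.46 to 0.066 for miR-181d, -0.32 to 0.015 for miR-2374, -0.30 to 0.026 for miR-2413, -0.12 to 0.70 for miR-486, -0.24 to 0.14 for miR-2328-3p and -0.20 to 0.14 for miR-2412. The values of miR-19a, miR-29b, miR-181d, miR-1225-3p, miR-106b and miR-15b rest on signals at the floor or not well above background, so their turns give no direction. With normexp, the offset of 50 pulls dim miRNAs to the negative side, since the scaling percentile was larger in pregnant cows. Its mean log2 was 9.35 in pregnant and 9.05 in non-pregnant cows in the main run. The normexp turns of dim miRNAs therefore give no clear direction. How much of the turns this explains, and the cause of the others, was not tested.

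The percentile over all probes was not run, since it was negative on non-pregnant 1; the haemolysis index was not run as a covariate, since miR-23a was not detected on every array; slide row was not run as a block, since it follows group. Signal over background limits the comparison: 18 tested miRNAs lay at the floor on every non-pregnant array.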

Other observations

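The summed signal of miR-122, the main liver miRNA, was 48.8, 19.9 and 24.3 in pregnant 1, 2 and 4 and at the undetected value of 0.1 in pregnant 3, and 21.9, 3.26 and 12.7 in non-pregnant 1, 3 and 4.

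The first principal component of the 88 levels carried 63.0% of the variance, with pregnant 2 and pregnant 4 at 4.47 and 4.48, non-pregnant 1 at 1.49, pregnant 1 at -0.13, and pregnant 3, non-pregnant 3 and non-pregnant 4 at -3.70, -3.62 and -2.98. The most alike arrays were pregnant 3 and non-pregnant 3 (r = 0.997 across 40 miRNAs, which are not independent replicates). Dark corner control spots averaged 294.3 on non-pregnant 3 and at most 5.48 on the other arrays.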
